A study of Mus musculus with 24 samples.

How the data were processed

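RNA from the cortex of 24 mice was measured on 24 arrays, 1 per mouse. The labels place the mice in 8 groups of 3: 4 inbred strains, named SV129, FVB, C57 and C3H, each given CBE or phosphate-buffered saline (PBS). The C57 mice were C57BL/6JOlaHsd per the study's design text. Per the labels' protocols, 1 mm coronal slices were made and the slice holding the cortex was frozen, total RNA was isolated with a column kit that includes DNase, and biotin-labelled fragments were prepared from 100 ng RNA with the GeneChip WT PLUS kit (Affymetrix). Partek and RMA (robust multi-array average) were used per the submitters' processing notes; their versions and the order of steps are not given in the sources used here. Scanner files were not used here.

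The deposited values are on a log2 scale, 1 per probe set and array, for 41034 probe sets. The base of the logarithm is not stated in the sources used here and was inferred: the highest value, 14.09, is 17442 as a power of 2, within the 65535 steps of a 16-bit scanner, and 1316253 as a power of e. Array medians lay between 4.14 and 4.22 and upper quartiles between 6.11 and 6.24, so the arrays lay on a similar scale without sharing 1 distribution, and the values are not centred per gene. In SV129 the 3 PBS medians (4.14 to 4.17) lay below the 3 CBE medians (4.19 to 4.22). Pearson correlations between arrays of 1 group ran from 0.992 to 0.997. Array values carry no count of molecules; the number of arrays limits the precision, and the median standard error of a log2 change was 0.10 within a strain and 0.05 for the mean of 4 strains. Probe sets near the lower end of the scale can hide or shrink a change.

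Gene symbols came from the platform annotation, which can be old. Of the probe sets, 23521 had 1 symbol, 1814 had several and 15699 had none given; only those with 1 symbol were named. Where a gene had several probe sets, as 1082 genes had, the one with the highest mean over the 24 arrays was used, which left 22180 genes. No filter on dim probe sets was applied. Genome positions are not given because no build was named in the sources used here; a gene is identified by its symbol and probe set number. Some genes that would belong to the lists below are not analysed here.

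All tests used limma 3.58.1 in R 4.3.3 on the deposited log2 values, with 1 mean per group, all 24 arrays in 1 fit, and moderated variances (16 residual degrees of freedom plus a prior of 5.10). The 8 groups shared 1 estimate of the spread because each held 3 arrays. Contrasts were CBE minus PBS in each strain, the mean of those 4 differences, an F-test of whether the 4 differences were equal (the interaction of strain and agent) with its 6 pairwise contrasts, and an F-test of the 4 PBS groups. Tests were two-sided, Benjamini-Hochberg adjustment ran over the 22180 genes within a contrast, and 0.05 was the threshold. Between 3 and 3 arrays an exact permutation test cannot give a p below 0.1, so the single-strain tests lean on the spread shared by the 8 groups. Correlations of changes between strains were taken across genes, which are not independent replicates, and carry no p.

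Lists of genes for 39 pathways, cell types and brain regions, holding 704 entries, were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes; 631 entries were measured, 1 of them through an older symbol. The lists of erythroid cells and of mitochondrially encoded transcripts had 1 and 0 measured members and were not tested, so blood in the vessels and RNA quality could not be judged from them. For each of the other 37 lists the mean log2 value of the members on an array was its score, and scores were tested with the same limma design, adjusted over the 37 lists. Beside it ran camera, which compares a list with all other genes, with the correlation between genes preset at 0.01 and with the correlation estimated per list, and fry, which asks whether members move on balance one way. Members were also counted after adjustment over the list alone.

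Genes were named by this rule. For the mean of 4 strains, the 12 largest rises and 12 largest falls past the threshold with the same direction in all 4 strains were taken. For each strain, the 6 largest rises and 6 largest falls past the threshold whose 3 CBE arrays did not overlap the 3 PBS arrays were taken. For differences between strains, the 10 smallest interaction p-values and the 2 largest past-threshold differences per strain pair were taken, and for PBS mice the 8 smallest p-values with a few label-check genes. Up to 4 members per list past the threshold were taken, or the 2 of smallest p where none passed, and Gba2, Ugcg, Gfap, Cd68 and Gpnmb were always taken. Predicted genes, clones, small RNAs, receptor families and antigen receptor segments were counted but not named.

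The procedure was tested on simulated data built from each gene's PBS means and residual spread, with 67, 67 and 66 of 22180 genes changed by a log2 of 0.5, 1 and 2. For the mean of 4 strains 95.5%, 100% and 100% of these were recovered, for SV129 71.6%, 100% and 100%, for FVB 73.1%, 98.5% and 100%, for C57 61.2%, 98.5% and 100%, and for C3H 74.6%, 100% and 98.5%. For the interaction the shares were 31.3%, 88.1% and 98.5%, and for the PBS strains 62.7%, 98.5% and 100%. False calls numbered 18 of 215 calls for the mean, 17 of 198 for SV129, 8 of 189 for FVB, 8 of 181 for C57, 13 of 195 for C3H, 3 of 148 for the interaction and 10 of 184 for the PBS strains. All 6 lists moved by 0.4 were recovered, with 0 false calls among lists sharing no member with them. The simulated genes varied independently, while members of measured lists moved together, with an estimated correlation of 0.82 in the myelin list. This list recovery therefore does not show how the test performs on the measured lists.

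Alternatives were 2 filters on dim genes, every probe set, the mean of a gene's probe sets, an intensity trend, an ordinary linear model without moderation, quantile normalization applied again, centring arrays on their median, array weights, the replicate number as a block, a fold threshold of 1.5, only the arrays of a comparison, other list scores, rank correlation, and leaving out each array in turn. Another 2 were added after the data were seen: leaving out C3H CBE array 1, which stood apart from its replicates in the list scores, together with SV129 PBS array 2, which had the lowest array weight, and averaging FVB, C57 and C3H only. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.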

Results

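Gene expression was measured in the cortex of 24 male mice aged 18 days, 1 array per mouse. The study models neuronopathic Gaucher disease, an inherited lysosomal storage disorder, by giving CBE (conduritol B-epoxide), an inhibitor of the lysosomal enzyme that is deficient in the disease. Mice of 4 strains, SV129, FVB, C57 and C3H, received CBE at 25 mg per kg per day by intraperitoneal injection from day 8 to day 18, or PBS, and the PBS mice served as healthy controls. Each of the 8 groups held 3 mice. Arrays are named by group and replicate number. The sex labels were checked: Xist, which is transcribed in females, lay between 3.17 and 3.48 on every array, and the Y-linked genes Eif2s3y, Kdm5d and Uty lay between 5.42 and 8.82. All 24 arrays matched the PBS profile of their own labelled strain best, each left out of that profile; the genes compared had been chosen on the PBS arrays, so only the 12 CBE arrays are independent of that choice. The arrays hold log2 signal; changes below are log2 CBE minus PBS with the standard error of the limma fit, and adjusted p is Benjamini-Hochberg.

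The first comparison asked which genes CBE changed on average over the 4 strains, 12 CBE against 12 PBS mice. CBE raised genes that cells switch on in response to interferon, the antiviral signalling proteins. It also raised chemokines, which attract immune cells, and genes of microglia, complement and antigen presentation. The score of the reactive astrocyte list rose as well, with 1 of its 27 members, Gfap, past the threshold. Fewer genes fell, and by less. Of 22180 genes, 161 changed, 135 up and 26 down, and 61 of them by at least 1.5-fold. Of the 135, 120 were higher in all 4 strains and 79 were above their strain's PBS mean on all 12 CBE arrays. Of the 26, 21 were lower in all 4 strains and 9 lay below on all 12. The genes were called on these same arrays, so part of this agreement is built in. In the mean of FVB, C57 and C3H, an average chosen after the data were seen, 153 genes were up and 7 down. The number of genes that changed was 244 without C3H CBE array 3, against 161 with every array.

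Interferon-stimulated genes carried the largest rises. Their list score rose by 1.02 ± 0.09 (adjusted p = 3.6e-08), 22 of 26 measured members rose and 25 did when adjusted over the list alone. Ifit1 (probe set 17358832), which binds viral RNA, rose by 2.58 ± 0.15 (adjusted p = 1.7e-09), from PBS means of 4.22 in SV129, 4.46 in FVB, 5.57 in C57 and 4.94 in C3H. The median of all probe sets was 4.18, so the lower of these lay near background, which compresses a rise. Oasl2 (17441037), a relative of the enzymes that sense double-stranded RNA, rose by 2.18 ± 0.17, and Usp18 (17462437), which removes Isg15 from proteins, by 2.09 ± 0.15. Isg15 (17434023) itself rose by 1.34 ± 0.09 and Rtp4 (17324446), an interferon-induced chaperone, by 1.37 ± 0.11. Lgals3bp (17272785), a secreted glycoprotein, rose by 1.72 ± 0.15. These 6 genes were higher on 12 of 12 CBE arrays, with adjusted p from 1.7e-09 for Ifit1 to 2.2e-07 for Lgals3bp.

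Chemokines and cytokines followed, with a list score up by 0.50 ± 0.05 (adjusted p = 5.9e-08). Of 22 members 8 rose, and 13 when adjusted over the list alone. Cxcl13 (17439367), which attracts B cells, rose by 1.89 ± 0.18, and Ccl5 (17266946) and Ccl3 (17266967), which attract T cells and monocytes, by 1.84 ± 0.14 and 1.62 ± 0.23. Cxcl10 (17449718), an interferon-induced attractant of T cells, rose by 1.43 ± 0.11. All were higher on 12 of 12 CBE arrays, with adjusted p from 5.3e-08 for Ccl5 to 2.6e-04 for Ccl3. Scores of blood cell markers did not pass: the lymphocyte score changed by 0.03 (adjusted p = 0.25) and that of monocytes and neutrophils by 0.02 (adjusted p = 0.55). By camera the lymphocyte list passed upward with the preset correlation (adjusted p = 0.037) but not with an estimated one (0.20).

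Genes of microglia and phagocytes also rose. The myeloid and phagocyte receptor score rose by 0.42 ± 0.09 (adjusted p = 9.3e-04), with 4 of 17 members up and 16 when adjusted over the list alone. Fcgr1, a high-affinity antibody receptor, rose by 0.81 and Fcer1g, its signalling chain, by 0.71. The disease-associated microglia list, genes that microglia switch on around damage and storage, rose by 0.37 ± 0.10 (adjusted p = 0.0076), with 4 of 25 members up and 16 when adjusted over the list alone. Its members Cd52, Cst7, Cd68 and Ctsz rose by 0.93, 0.84, 0.75 and 0.68. In an ordinary linear model Fcer1g (0.052), Cst7 (0.079), Cd68 (0.076) and Ctsz (0.12) lost their calls. C3H CBE array 1 stood far above its replicates in both lists, and without it the mean rises were 0.33 for myeloid receptors and 0.27 for disease-associated microglia. Lilrb4a (17233226), an inhibitory receptor of myeloid cells, rose by 2.08 ± 0.30 (adjusted p = 3.5e-04) and Cybb (17540154), the catalytic subunit of the phagocyte oxidase, by 1.33 ± 0.18 (adjusted p = 2.1e-04). Lilrb4a has a near-identical neighbour, so the identity of its signal is uncertain. Gpnmb, a marker of storage-laden macrophages, changed by 0.70 ± 0.26 (adjusted p = 0.29). Without C3H CBE array 1 its change differed between strains by the F-test of equal changes (adjusted p = 0.0090). It was then 1.25 in C57, 0.48 in C3H, 0.01 in SV129 and -0.09 in FVB. The homeostatic microglia score rose by 0.11 ± 0.04 (adjusted p = 0.046), with 1 of 13 members up, Csf1r, and 2 when adjusted over the list alone. By camera its adjusted p = 0.12 with an estimated correlation, and leaving out any of 15 single arrays ended its call (0.055 to 0.094).

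Complement, which tags material for removal by phagocytes, rose by 0.40 ± 0.07 (adjusted p = 9.7e-05), with 7 of 14 members up and 10 when adjusted over the list alone. C4b (17343918) rose by 1.23 ± 0.18 and C1qb (17431607) by 0.93 ± 0.11, while C3ar1 and C1qa rose by 0.72 and 0.63. C4b is nearly identical to a neighbouring gene, which leaves its identity uncertain. The antigen presentation list, which displays peptides to T cells, rose by 0.40 ± 0.06 (adjusted p = 2.3e-05), with 6 of 14 up and 11 when adjusted over the list alone. H2-K1 rose by 0.95, B2m by 0.84, the peptide transporter Tap1 by 0.63 and the proteasome subunit Psmb8 by 0.47. Without C3H CBE array 1 the change of B2m differed between strains by the F-test of equal changes (adjusted p = 0.0012). It was then -0.12 in SV129, 1.65 in FVB, 0.75 in C57 and 0.61 in C3H. The H2 class I genes resemble one another, which leaves the identity of H2-K1 and H2-Q4 uncertain. Sensors of microbial and self molecules rose by 0.17 ± 0.03 (adjusted p = 6.3e-04), with 4 of 19 up and 9 when adjusted over the list alone; Tlr7, Casp1, Tlr2 and Tlr3 rose by 0.53, 0.37, 0.35 and 0.20. C3ar1 (0.060) and Casp1 (0.064) lost their calls in an ordinary linear model.

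Outside the immune lists, Gfap (17270354), the filament protein of reactive astrocytes, rose by 1.15 ± 0.13 (adjusted p = 2.8e-05). The reactive astrocyte score rose by 0.20 ± 0.05 (adjusted p = 0.0085), with 1 of 27 members up and 6 when adjusted over the list alone. The lysosome list rose by 0.21 ± 0.06 (adjusted p = 0.0085), with 4 of 32 up and 11 when adjusted over the list alone. By camera its adjusted p = 0.079 with an estimated correlation. Among its members the proteases Ctss and Ctsc rose by 0.78 and 0.76. C3H CBE array 1 stood far above its replicates in the reactive astrocyte and lysosome lists. Without it the mean rises were 0.14 for reactive astrocytes and 0.15 for the lysosome. The necroptosis and death receptor list rose by 0.12 ± 0.04 (adjusted p = 0.015), with 1 of 12 up, Zbp1, which is also on the interferon-stimulated list, and 2 when adjusted over the list alone; Zbp1 lost its call in an ordinary linear model (0.064). By camera the necroptosis list had adjusted p = 0.065 with an estimated correlation. The glucocorticoid-responsive list rose by 0.12 ± 0.04 (adjusted p = 0.014) with 0 of 12 members past the threshold, 0 when adjusted over the list alone; Sgk1 changed by 0.20 and Fkbp5 by 0.23. With the median of members as its score its adjusted p was 0.11. Of the 13 lists that changed, 9 held by camera, which compares a list with all other genes, with an estimated correlation.

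Falls were small. Cholesterol biosynthesis, a lipid supply route of neurons and glia, fell by 0.11 ± 0.04 (adjusted p = 0.037), was lower on 10 of 12 CBE arrays, and had 1 of 19 members down, Stard4, and 5 when adjusted over the list alone. By camera its adjusted p = 0.16 with an estimated correlation, and in the mean of FVB, C57 and C3H the score gave 0.058. Leaving out any of 11 single arrays ended this call: SV129 PBS 1 and 3, SV129 CBE 3, FVB PBS 1 and 2, FVB CBE 1, C57 PBS 1, C57 CBE 3, C3H PBS 1 and 3 and C3H CBE 1, with adjusted p from 0.053 to 0.079, and with the median of members it was 0.25. Stard4 (17353358), a cholesterol carrier, fell by 0.29 ± 0.05 (adjusted p = 0.0085) and Lrp1b (17384826), a lipoprotein receptor relative, by 0.26 ± 0.04 (adjusted p = 0.0011), both lower on all 12 CBE arrays. Zfp667, Spink10, Gabrg1, Trpc7 and G3bp1 fell by 0.28, 0.28, 0.28, 0.27 and 0.26. In the mean of FVB, C57 and C3H the calls of Zfp667 (0.37), Spink10 (0.15), Gabrg1 (0.34) and G3bp1 (0.13) were lost, as were those of Hspa1b (0.20), Zik1 (0.33) and Efhc2 (0.10). Gabrg1 also lost its call in an ordinary linear model (0.052) and after quantile normalization (0.058). Hspa1b (fell by 0.33), Zik1 (fell by 0.29), Efhc2 (fell by 0.26), Mex3b (fell by 0.24) and Tbc1d32 (fell by 0.24) lost the call when any of 16, 16, 9, 18 and 9 single arrays was left out, to adjusted p of at most 0.084, 0.102, 0.061, 0.088 and 0.057. Hspa1b is nearly identical to Hspa1a. Csf1r and Ctsz, named above, likewise lost theirs without any of 12 and 13 arrays, to an adjusted p of at most 0.079 and 0.068.

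The disease model acts on glucosylceramide, and the glycosphingolipid list changed by -0.03 (adjusted p = 0.27), with Gba2 at -0.09 (adjusted p = 0.37), Ugcg at -0.12 (adjusted p = 0.36) and Galc at -0.19 (adjusted p = 0.25). Autophagy changed by -0.01, the unfolded protein and integrated stress response by 0.01, oxidative stress and NRF2 targets by 0.04, p53 targets by 0.04 and LXR targets by 0.01, where the median member was -0.01. Neuronal lists also missed the threshold: inhibitory interneurons 0.00, excitatory cortical neurons -0.04, pan-neuronal and synaptic genes -0.04, calcium channels, pumps and buffers -0.01, and immediate-early genes -0.13. Oligodendrocyte and myelin genes changed by -0.11 ± 0.14 and oligodendrocyte precursors by -0.07. Astrocyte markers changed by 0.03, endothelial cells by 0.03, pericytes and smooth muscle by 0.03, meninges and fibroblasts by -0.05, and cell cycle genes by 0.05. Lists of neighbouring regions did not pass either: choroid plexus and ependyma 0.02, with a median member of -0.02, striatum -0.13, thalamus -0.03 and hippocampus 0.01. Adjusted p for these lists ran from 0.075 for the cell cycle to 0.95 for interneurons.

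**Figure D1:**
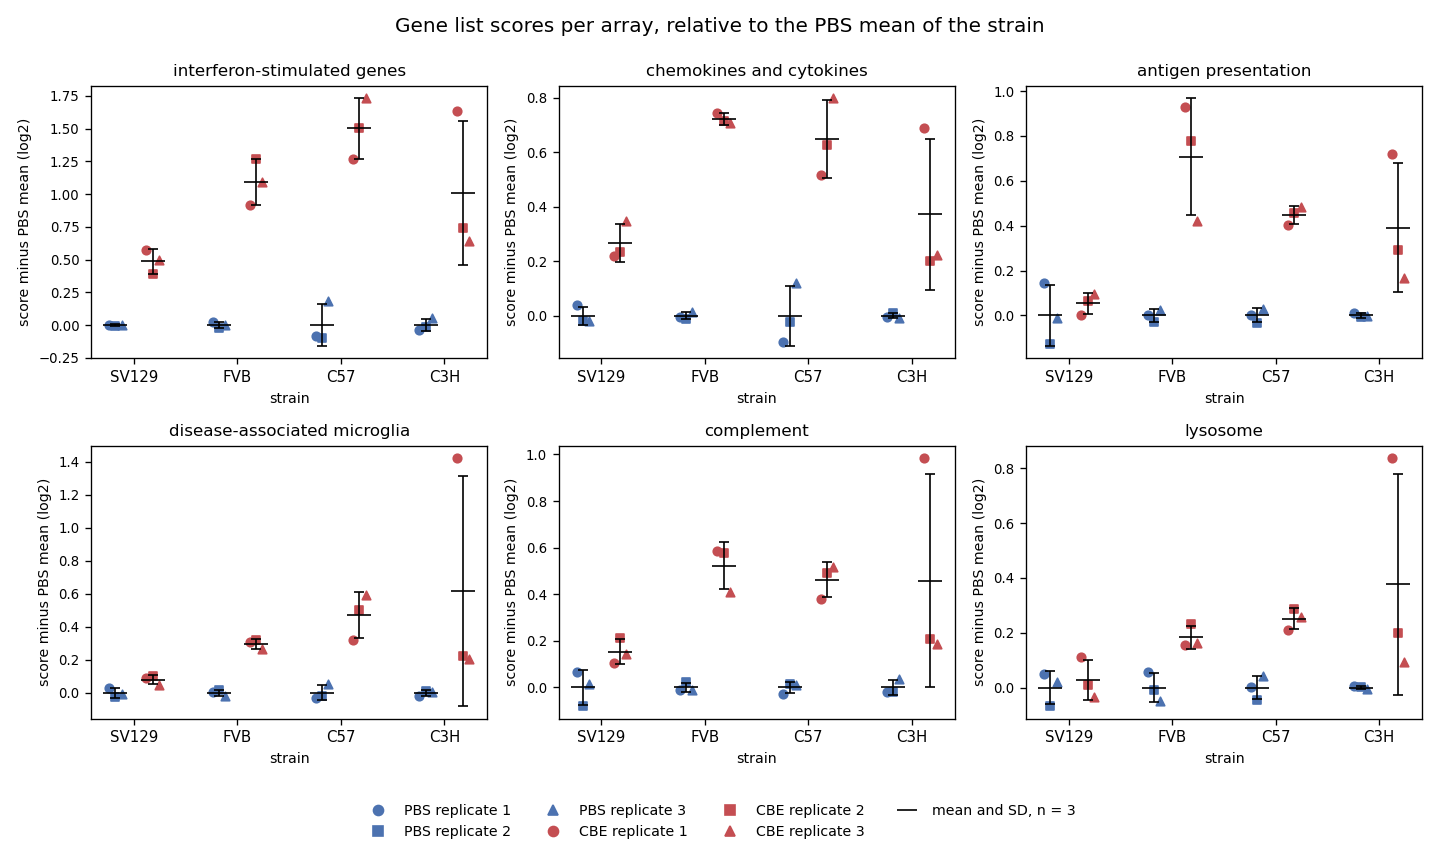
Score of 6 gene lists per array, as log2 minus the mean of the strain's PBS arrays, with group mean and SD (n = 3). The interferon-stimulated list rose by 0.49 in SV129, 1.09 in FVB, 1.501 in C57 and 1.01 in C3H; C3H CBE array 1 lay above its 2 replicates in the disease-associated microglia list, at 1.42 against 0.22 and 0.21.

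The response was then examined in each strain, 3 CBE against 3 PBS mice; an exact permutation test of 3 against 3 cannot go below p = 0.1, so these calls rest on the spread shared by the 8 groups. In SV129, more genes were lower than higher in CBE mice, and the immediate-early and thalamus lists were lower. These falls are not shown to come from CBE, since another split of the 6 arrays gave 23 genes against the real 25. Meanwhile the interferon-stimulated score changed by less than in the other 3 strains, a difference that passed its test against C57 and, without C3H CBE array 1, also against FVB (-0.60, adjusted p = 0.0028). Of 22180 genes, 25 changed, 3 up and 22 down, and 2886 had an unadjusted p under 0.05. Chance alone gives a share of 0.05 of the genes tested such a p. Counts of unadjusted p, here and below, are therefore not numbers of changed genes. Ifit1 rose by 2.02 ± 0.30 (adjusted p = 0.0045), Isg15 by 0.97 ± 0.19 (adjusted p = 0.044) and Thrsp (17493432), a lipid synthesis regulator, by 0.60 ± 0.12 (adjusted p = 0.044). Falls were Atp6ap1l (17294775) by 1.32 ± 0.26, Nr4a3 (17413945), an activity-regulated transcription factor, by 1.24 ± 0.24, the integrin Itga4 (17372307) by 0.95 ± 0.14, and the surface proteins Tenm3 (17509315), Cntn6 (17461240) and Ntng1 (17409480) by 0.90 ± 0.16, 0.83 ± 0.12 and 0.82 ± 0.13. Among the lists 2 fell and 0 rose. The interferon score changed by 0.49 (adjusted p = 0.12), with 2 members up and 7 when adjusted over the list alone. Without C3H CBE array 1, 3 SV129 lists rose by the same amounts: interferon-stimulated genes (adjusted p = 0.0023), chemokines by 0.27 (adjusted p = 0.0027) and complement by 0.15 (adjusted p = 0.036).

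Single arrays decided much of the SV129 result. The count was 219 (43 up, 176 down) without SV129 PBS array 1, 8 without PBS array 2, 42 without CBE array 1, 7 without CBE array 2 and 11 without CBE array 3; with each array centred on its median it was 143 (7 up, 136 down). Itga4 lost its call without SV129 PBS array 2 (adjusted p = 0.052), Tenm3 without SV129 PBS array 2, CBE array 2 or CBE array 3 (0.063 to 0.158), and Ntng1 without CBE array 2 or 3 (0.063 to 0.093). Isg15, Thrsp, Atp6ap1l and Nr4a3 lost theirs without any of 12, 9, 14 and 8 single arrays, with adjusted p of at most 0.149, 0.175, 0.216 and 0.190. Ifit1 and Cntn6 kept theirs without any single array, but Ifit1 lost it in an ordinary linear model (0.051) and Cntn6 with only the strain's own arrays (0.29). With only those arrays Itga4 (0.12), Tenm3 (0.20) and Ntng1 (0.37) lost theirs too. The immediate-early list, genes that neurons switch on with activity, fell by 0.71 ± 0.18 (adjusted p = 0.020), with 1 of 21 members down, Nr4a3, and 12 when adjusted over the list alone; without SV129 PBS array 2, PBS array 3 or CBE array 2 its adjusted p lay between 0.098 and 0.212. The thalamus list fell by 0.22 ± 0.04 (adjusted p = 3.5e-04), with 1 of 11 members down, Ntng1, and 2 when adjusted over the list alone. Of its members 10 of 11 were lower, Ntng1 and Slc17a6 (-0.85, adjusted p = 0.066) the most, the latter chosen after its values were seen. Without Ntng1 the score changed by -0.16 (adjusted p = 0.022), and with the median of members as score by -0.02 (adjusted p = 0.97). The thalamus and immediate-early lists also differed among the PBS groups by the F-test (adjusted p = 8.1e-04 and 0.027). That test does not say which strain stood apart, so a difference in the SV129 PBS arrays stays open.

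**Figure D2:**
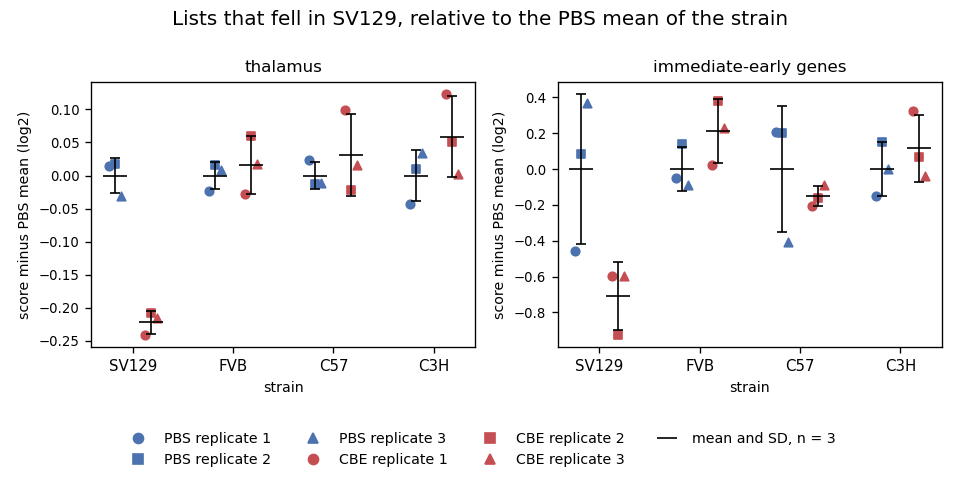
Scores of the thalamus and immediate-early lists per array, as log2 minus the mean of the strain's PBS arrays, with group mean and SD (n = 3). In SV129 the thalamus score changed by -0.22 and the immediate-early score by -0.71.

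In FVB, CBE raised the interferon-stimulated list most, followed by chemokines and antigen presentation, and the chemokine Cxcl13 most among the named genes. All 30 genes that changed rose, and 1390 had an unadjusted p under 0.05. Cxcl13 rose by 4.37 ± 0.36 (adjusted p = 1.1e-06), Ccl5 by 2.92 ± 0.29 (adjusted p = 1.5e-05), Ifit1 by 2.75 ± 0.30, Lgals3bp by 2.33 ± 0.29, Oasl2 by 2.28 ± 0.33 and Cxcl9 (17449710), another T cell attractant, by 2.26 ± 0.36 (adjusted p = 0.0038). Lists that rose were interferon-stimulated genes by 1.09 (adjusted p = 1.1e-04; 11 members up, 22 adjusted over the list alone), chemokines by 0.72 (adjusted p = 1.6e-05; 6 and 7), antigen presentation by 0.71 (adjusted p = 1.1e-04; 2 and 12), complement by 0.52 (adjusted p = 0.0070; 1 and 7) and pattern recognition by 0.28 (adjusted p = 0.0070; 1 and 6). The count was 85 without C3H CBE array 1. Each named gene and list of this strain kept its call without any single array. With the median of members as score chemokines and pattern recognition lost theirs (0.092 each), and Cxcl9 did with only the strain's own arrays (0.30). Without C3H CBE array 1 the disease-associated microglia list (0.30, adjusted p = 3.3e-05), myeloid receptors (0.44, adjusted p = 4.5e-06), the lysosome (0.18, adjusted p = 0.0020), reactive astrocytes (0.16, adjusted p = 0.0020), necroptosis (0.12, adjusted p = 0.046) and the unfolded protein list (0.09, adjusted p = 0.015) also passed.

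In C57, the interferon-stimulated list had the largest rise of the lists. Its rise did not pass for a difference from FVB (-0.41 for FVB minus C57, adjusted p = 0.78) or from C3H (0.49 for C57 minus C3H, adjusted p = 0.60). CBE changed 72 genes, 70 up and 2 down, with 1281 at an unadjusted p under 0.05. Ifit1 rose by 3.12 ± 0.30 (adjusted p = 5.5e-06), Lilrb4a by 3.04 ± 0.60 (adjusted p = 0.022), Oasl2 by 2.97 ± 0.33, Ccl5 by 2.70 ± 0.29, Usp18 by 2.68 ± 0.30 and Cxcl10 by 2.62 ± 0.22 (adjusted p = 1.1e-06). Cbln2, a synapse organiser, and Nup133, a nuclear pore protein, each fell by 0.44 ± 0.09 (adjusted p = 0.033 and 0.028). Acta2, of smooth muscle, rose by 0.86 (adjusted p = 0.032). The interferon list rose by 1.501 (adjusted p = 4.1e-06; 21 members up, 25 adjusted over the list alone) and chemokines by 0.65 (adjusted p = 3.6e-05; 5 and 8). Myeloid receptors rose by 0.57 (adjusted p = 0.030; 1 and 9), complement by 0.46 (adjusted p = 0.024; 0 and 6), antigen presentation by 0.45 (adjusted p = 0.014; 3 and 6) and pattern recognition by 0.22 (adjusted p = 0.030; 1 and 4). The count was 37 without C57 PBS array 1, 40 without PBS array 2, 44 without CBE array 2, 30 without CBE array 3 and 136 without C3H CBE array 1. Lilrb4a, Cbln2 and Nup133 lost their calls without C57 PBS array 1, 2 or 3 or CBE array 2 or 3, to adjusted p of at most 0.186, 0.313 and 0.219, and in an ordinary linear model (0.12, 0.083 and 0.067). The last 4 lists lost theirs, complement, myeloid and pattern recognition without C57 PBS array 1 or 2 or CBE array 2 or 3 (at most 0.099, 0.179 and 0.179), antigen presentation without PBS array 2 or CBE array 2 or 3 (at most 0.061). With the median of members chemokines (0.096), myeloid receptors (0.096), complement (0.096) and pattern recognition (0.16) lost theirs. Without C3H CBE array 1 the disease-associated microglia list (0.47, adjusted p = 1.1e-07), the lysosome (0.25, adjusted p = 8.9e-05), reactive astrocytes (0.25, adjusted p = 2.0e-05), necroptosis (0.20, adjusted p = 0.0012) and the cell cycle (0.11, adjusted p = 0.0017) also passed in C57.

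In C3H, the 6 genes named were all on the interferon-stimulated list, and microglial, lysosomal and astrocyte lists passed as well. CBE raised 8 genes and lowered 0. The number at an unadjusted p under 0.05, 1114, was about what chance gives over 22180 genes. Usp18 rose by 2.59 ± 0.30 (adjusted p = 4.9e-04), Ifit1 by 2.41 ± 0.30, Oasl2 by 2.28 ± 0.33, Lgals3bp by 1.83 ± 0.29, Ifi27 (17278200), an interferon-induced membrane protein, by 1.36 ± 0.21 and Rtp4 by 1.27 ± 0.22. The interferon list rose by 1.01 (adjusted p = 8.4e-04; 7 members up, 21 adjusted over the list alone). Disease-associated microglia rose by 0.62 (adjusted p = 0.028; 0 and 17), myeloid receptors by 0.59 (adjusted p = 0.026; 0 and 13), complement by 0.46 (adjusted p = 0.026; 0 and 7), antigen presentation by 0.39 (adjusted p = 0.026; 0 and 4), the lysosome by 0.38 (adjusted p = 0.028; 0 and 11), chemokines by 0.37 (adjusted p = 0.017; 0 and 4), reactive astrocytes by 0.31 (adjusted p = 0.049; 0 and 2) and the cell cycle by 0.14 (adjusted p = 0.029; 0 and 2). C3H CBE array 1 stood apart: its interferon score lay 1.64 above the PBS mean against 0.74 and 0.64 in its replicates, and its lysosome score 0.84 against 0.20 and 0.09. The count was 4 without C3H PBS array 1, 3 without PBS array 2, 21 without CBE array 2 and 52 without CBE array 3; using only the strain's own 6 arrays it was 0. Lgals3bp lost its call without C3H PBS array 1 or 2 (at most 0.109), Ifi27 without PBS array 2 or 3 (at most 0.060) and Rtp4 without PBS array 1, 2 or 3 or CBE array 1 (at most 0.218). In an ordinary linear model Oasl2 (0.084), Lgals3bp (0.13), Ifi27 (0.091) and Rtp4 (0.19) lost theirs. Of the lists only the interferon list kept its call without any single array; the others lost theirs without C3H PBS array 1, 2 or 3, cell cycle and antigen presentation also without CBE array 1 (0.19 and 0.17), and reactive astrocytes without any of 22 arrays (at most 0.20). Without CBE array 1 the disease-associated microglia score changed by 0.21 (adjusted p = 0.011), myeloid receptors by 0.24 (adjusted p = 0.017), complement by 0.20 (adjusted p = 0.017), chemokines by 0.21 (adjusted p = 0.030), the lysosome by 0.15 (adjusted p = 0.043), reactive astrocytes by 0.09 (adjusted p = 0.20), antigen presentation by 0.23 and the cell cycle by 0.06. With the median of members disease-associated microglia (0.13), myeloid receptors (0.090), the lysosome (0.090), reactive astrocytes (0.14) and the cell cycle (0.13) lost their calls.

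**Figure D3:**
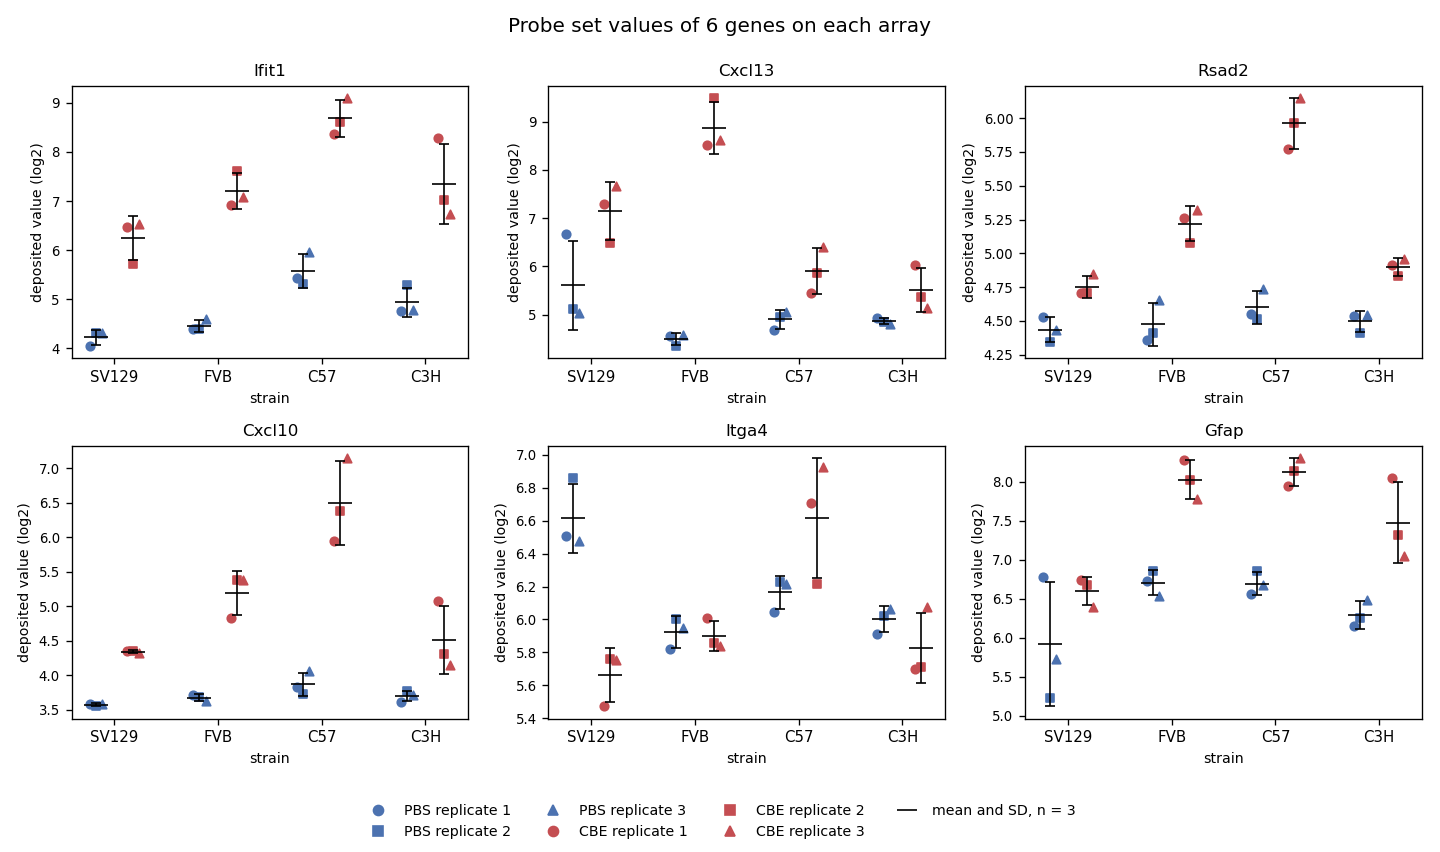
Log2 signal of Ifit1, Cxcl13, Rsad2, Cxcl10, Itga4 and Gfap on each array, with group mean and SD (n = 3). Cxcl13 rose by 4.37 in FVB and changed by 0.65 in C3H, and Itga4 fell by 0.95 in SV129.

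Whether the response to CBE differed between strains was tested as the interaction of strain and agent, since a gene past the threshold in one strain only does not show a difference. The chemokine Cxcl13 had its largest change in FVB, and the antiviral gene Rsad2 (17280327) in C57. Neither was shown to exceed every other strain: Cxcl13 in FVB did not pass against SV129, nor Rsad2 in C57 against FVB. These 2 genes passed the interaction test, each at adjusted p = 0.0102, with 1458 at an unadjusted p under 0.05. Cxcl13 changed by 1.54 in SV129, 4.37 in FVB, 1.00 in C57 and 0.65 in C3H, and Rsad2 by 0.32, 0.74, 1.36 and 0.41. Next were Ccl5 and Itga4 (0.057), Cxcl10 (0.079), Cntn6 (0.094), H2-Q4 (0.14), Cxcl11 and Lct (0.17) and Ifi30 (0.19), which did not pass. Between SV129 and C57, 8 genes differed, 2 with the larger value in SV129: Itga4 by -1.40 ± 0.20 (adjusted p = 0.0071), Rsad2 by -1.04 ± 0.14 (adjusted p = 0.0046), Cxcl10 by -1.86 ± 0.31 (adjusted p = 0.035) and Ifi30, a lysosomal reductase of antigen processing, by -1.59 ± 0.27 (adjusted p = 0.035) were among them. Cxcl13 differed by 3.37 ± 0.51 between FVB and C57 (adjusted p = 0.029) and by 3.72 ± 0.51 between FVB and C3H (adjusted p = 0.0067), and Rsad2 by 0.96 ± 0.14 between C57 and C3H (adjusted p = 0.018). Between SV129 and FVB 0 genes passed, with 1772 at an unadjusted p under 0.05, and between SV129 and C3H 0, with 1705.

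Among lists only the thalamus list differed by the interaction test (adjusted p = 0.00398), lower in SV129 than in FVB by -0.24 ± 0.05 (adjusted p = 0.0080), in C57 by -0.25 (adjusted p = 0.0042) and in C3H by -0.28 (adjusted p = 0.0013); with the median of its members the interaction gave 0.77, and without Ntng1 0.071. With the median of members it was the immediate-early list that differed (interaction 0.022, SV129 change -0.99 with adjusted p = 0.0023). By mean scores interferon-stimulated genes, chemokines, antigen presentation and immediate-early genes each gave 0.071. In pairs, the interferon score rose by less in SV129 than in C57 (-1.01 ± 0.25, adjusted p = 0.014). The score in PBS mice was 4.53 in SV129 and 5.13 in C57, and signal nearer background compresses a rise. Whether this made the gap was not tested. The changes of antigen presentation (-0.65 ± 0.16, adjusted p = 0.015), chemokines (-0.45 ± 0.13, adjusted p = 0.029) and immediate-early genes (-0.92 ± 0.26, adjusted p = 0.027) were lower in SV129 than in FVB. Between SV129 and C3H no immune list passed, with the interferon difference at -0.52 (adjusted p = 0.31). Rsad2 lost its interaction call without C57 PBS array 2 (0.064), and Cxcl13 without FVB PBS array 2, FVB PBS array 3, FVB CBE array 2 or C57 PBS array 2 (0.050 to 0.089). Both lost it with every probe set tested (0.070 for Rsad2 and 0.071 for Cxcl13) and in an ordinary linear model (0.11 and 0.31). The gene count was 25 without C3H CBE array 1, 6 without SV129 CBE array 3, 4 without C57 CBE array 1 or C3H CBE array 3, 1 without FVB PBS array 2, FVB PBS array 3 or FVB CBE array 2, and 0 without C57 PBS array 2. The list count was 11 without C3H CBE array 1, 3 without C3H CBE array 3 and 2 without SV129 PBS array 1, FVB CBE array 3 or C57 PBS array 3. Cxcl10 and Ifi30 between SV129 and C57, Cxcl13 between FVB and C57 and Rsad2 between C57 and C3H lost their calls without any of 13, 12, 13 and 7 single arrays, to at most 0.125, 0.125, 0.157 and 0.111.

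How far the strains shared their response was also measured. Ifit1 and Isg15 passed the threshold as rises in all 4 strains, 5 genes in 3, 12 in 2 and 64 in 1, which does not show that those 64 rose in 1 strain only. FVB and C57 shared 18 rising genes past the threshold, where chance gives 0.0947, FVB and C3H shared 8 (0.0108) and C57 and C3H 7 (0.0252). Over the 153 genes that rose in the mean of FVB, C57 and C3H, the median change was 0.14 in SV129 against 0.66 in those strains, and 123 changed in the same direction. Genes chosen for rising in 3 strains tend to be lower in the one left out, so the same was done for each strain. FVB had 0.67 against 0.70, C57 1.02 against 0.72 and C3H 0.58 against 0.68. Genes that fell in the mean of the other strains carried over less in FVB, C57 and C3H. The same direction was held by 11 of 18 in FVB, 11 of 22 in C57, 16 of 23 in C3H and 6 of 7 in SV129. Their median changes were -0.03 against -0.29 in FVB and 3.2e-04 against -0.30 in C57. They were -0.06 against -0.28 in C3H and -0.15 against -0.25 in SV129. Across genes, which are not independent replicates, log2 changes correlated between FVB, C57 and C3H at Pearson r of 0.33 to 0.38, and between SV129 and each of them at 0.11 to 0.14. Rank correlations did not set SV129 apart: they were 0.0925 with FVB, 0.0176 with C57 and 0.0754 with C3H, against 0.0766 to 0.108 among the other strains. No control arrays were shared between strains.

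The last comparison asked how the strains differed without CBE, among the 12 PBS mice. Strain differences were far more numerous than changes with CBE, and of the 8 genes with the smallest p only Herc6 also passed for CBE. By the F-test 2883 genes differed; C57 stood farthest from the rest, with 1755 genes between FVB and C57 and 1712 between SV129 and C57, against 506 between FVB and C3H. Baiap2l1 (17454977), an actin regulator, had a PBS mean of 6.68 in C3H against 3.73 to 3.80 in the others (adjusted p = 8.1e-14). Fam205a2 (17413094), whose family members are nearly identical, had 8.06 in C57 against 4.63 in SV129. Herc6 (17458962), the interferon-induced ligase that attaches Isg15, had 5.27 in SV129 and 6.91 to 7.60 in the others (adjusted p = 1.6e-10), and rose with CBE by 0.49 over the strains. Zfp605, D5Ertd579e, Myo7a, Gdpd3 and Esco1 completed the 8, with adjusted p from 1.1e-10 to 2.8e-09. Of 37 lists 8 differed: thalamus (8.1e-04), unfolded protein (0.013), calcium (0.013), glucocorticoid (0.026), immediate-early (0.027), interferon-stimulated (0.037), p53 (0.037) and myelin (0.037). The interferon score in PBS mice was 4.53 in SV129, 4.50 in FVB, 5.13 in C57 and 4.68 in C3H. A strain variant under a probe shifts its signal without a change in expression, so a difference in a single gene is not shown to be one of expression. The same limit holds for the counts of differing genes and for the distance of C57 from the rest. Of the other label-check genes, Mmrn1 and Hc lay near the floor in every strain and Nnt lay between 6.32 and 6.72.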

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

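The tests chosen only after the result was seen were those of an SV129 array out of place, of PBS and CBE arrays exchanged within SV129, of strain variants under the probes, of blood cells in the tissue and of array-wide noise. The bound for blood cells was also moved, from 2 SD to 1 SD, after its value was known, the test of an SV129 array out of place was made stricter after its value was known, and the strain variant test was replaced 2 times after it had been run, with its minimum of 10 genes set after the count of 4 was known.

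The response of Cxcl13 and of Rsad2 to CBE differed between strains by the interaction test (adjusted p = 0.0102 each). Cxcl13 responded more in FVB than in C57 by 3.37 and than in C3H by 3.72, and Rsad2 responded more in C57 than in C3H by 0.96. Between SV129 and C57, 8 responses differed: Cxcl10 by -1.86, Ifi30 by -1.59, Rnf213 by -1.42, Itga4 by -1.40, 4930429F24Rik by -1.11, Rsad2 by -1.04, Taar7e by 0.91 and Psg20 by 0.69, of which Rnf213, 4930429F24Rik, Taar7e and Psg20 were named only after their values were seen. The thalamus list differed between strains (adjusted p = 0.00398). Among 17513 probe sets without a single gene symbol, which were tested apart from the named genes, 15 changed with CBE in the mean of 4 strains, 14 up and 1 down, 9 of them with several symbols; the largest rise was 2.73 and the largest fall -0.51, 1079 had an unadjusted p under 0.05, and 0 passed the interaction.

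Other splits of the arrays were counted. Chance can be excluded for the genes that changed in the mean of 4 strains (161, highest of 99 other splits 2). There 1 of 100 splits was as large, the real one. The same holds for lists (13, highest other 2) and for the PBS strains (2883, highest other 669). The interaction held 2 genes against 1 in the highest other. That gap is too narrow to exclude chance, since 0 genes passed without C57 PBS array 2. SV129 against C57 held 8 (highest other 2). This pair had the most calls of the 6 pairs, and the reassignments counted it alone, so chance is not excluded there. For lists that differed between strains 4 of 100, the real one included, gave as many (1, highest other 1). Within a strain, 10 splits are too few for a share under 0.05: the real value and highest other were 25 and 23 in SV129, 30 and 1 in FVB, 72 and 1 in C57, and 8 and 0 in C3H.

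Falls dominated in SV129, with 22 of 25 genes down and a median of -0.60. A single array out of place stays open: leaving out any SV129 array left at least 0.989 of the median fall, but the genes had been chosen with all arrays, and the number that fell dropped to 7 without PBS array 2, 6 without CBE array 2 and 9 without CBE array 3, and rose to 176 without PBS array 1. A variation between arrays that also runs through the other strains stays open: the largest correlation across genes with its components was 0.144, against 0.199 in FVB, 0.344 in C57 and 0.083 in C3H. A different sampling of the cortex, which could bring more or less thalamus, also stays open, since the falling genes correlated with the thalamus score over the other strains' arrays at a median of 0.202, with a range from -0.44 to 0.60. These cannot be told apart from a response of the strain to CBE, which the design names and no test here separates.

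The genes that rose elsewhere changed less in SV129, at 0.210 of the median elsewhere over 153 genes of any kind, where leaving out FVB, C57 or C3H instead gave 0.960, 1.41 and 0.848, and the interferon score rose by less than in C57; the gap to C3H is not shown, since without C3H CBE array 1 chemokines changed by 0.27 in SV129 and 0.21 in C3H and interferon-stimulated genes by 0.49 and 0.69 (difference adjusted p = 0.83). For the interferon list a higher starting level is argued against, since its score in SV129 PBS mice lay -0.239 from the mean of the other strains (within-group SD 0.230). C57 at 5.13 raised that mean, and SV129 at 4.53 lay near FVB at 4.50. A rise compressed by a start nearer background than that of C57 was not tested and stays open. FVB started as low and its score rose by 1.09. For the other rising genes a higher starting level was not tested and stays open. SV129 PBS array 1 lay above its replicates in Gfap and Cxcl13, as given below. Exchanged PBS and CBE arrays are argued against, since the lowest SV129 CBE array lay 0.385 above the highest SV129 PBS array. Strain variants under the probes stay open: over genes not lower in SV129 across all its arrays the response was 0.151 of that in the other strains, but only 4 genes were left, and earlier versions gave 0.203 over 11 genes chosen by SV129 PBS level, which biases the change downward, and 5 of 31 genes (16.1%) over 0.5 lower in SV129 PBS mice. They cannot be told apart from a smaller response of the strain to CBE.

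C3H CBE array 1 stood apart from its replicates, 1.21 above them in the disease-associated microglia score, or 21.4 within-group SD. A wrong strain label is argued against, since its correlation with the C3H profile exceeded that with any other strain by 0.608. Array-wide noise, over most genes, is argued against, since its median deviation over genes in no list was 1.02 times the median of the other arrays. That median leaves aside genes that deviate strongly. Over all genes its root mean square residual was 0.151, near the top of the range of the arrays (0.104 to 0.151). Noise in fewer genes was not tested. Blood cells in the tissue stay open: the monocyte and neutrophil score lay 1.70 SD above its replicates and the lymphocyte score -0.53. No biological explanation was tested, because the design puts this array in the same group as its replicates.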

How the results depend on the processing

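Only the alternatives that left out C3H CBE array 1 with SV129 PBS array 2, or averaged FVB, C57 and C3H alone, were chosen after the result was seen. Leaving out C3H CBE array 1 alone was planned like that of every array, but it was singled out after its list scores were seen. No called result reversed. Of 96 called changes of named genes 44 lost the call under at least 1 alternative, as did 17 of 22 list calls in single strains. Of 13 lists in the mean, homeostatic microglia, cholesterol biosynthesis and glucocorticoid-responsive genes lost theirs under other scores or arrays, and the lysosome and necroptosis lists by camera with an estimated correlation, which called 9 lists; fry called 12 and camera with a preset correlation 18. Values that changed past 1.5 times are given by alternative, and the cause was not tested unless stated.

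The milder filter on dim genes gave 4 interacting genes, and the stricter one gave 60 genes in SV129, 4 interacting genes and a correlation of changes between strains of 0.301, with fewer genes tested. Every probe set gave 0 interacting genes and a correlation of 0.123, and rank correlation gave 0.0777, against 0.242. An intensity trend gave 13 genes in C3H and 5 interacting genes. An ordinary linear model gave 7 genes in SV129, 36 in C57, 2 in C3H and 0 interacting genes. Quantile normalization gave 13 genes in C3H and 4 interacting lists, median centring 143 genes in SV129 (7 up, 136 down), 6 interacting genes and 5 lists, array weights 112 genes in C57 and 3 lists, and scaled members 2 lists. At least 1.5-fold left 61 genes in the mean, 16 in SV129 and 1026 between PBS strains by construction. Only the comparison's arrays gave 4 genes in SV129, 58 in FVB and 0 in C3H. Without both doubted arrays there were 12 genes in SV129, 87 in FVB, 129 in C57, 4 in C3H, 16 interacting genes and 11 lists. The mean of FVB, C57 and C3H gave 160 genes (153 up, 7 down) and 13 lists.

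Leaving out 1 array at a time, genes in the mean ranged from 132 to 244, SV129 from 7 to 219, FVB from 25 to 85, C57 from 30 to 136, C3H from 3 to 52, the interaction from 0 to 25, PBS strains from 1993 to 3044, the correlation from 0.192 to 0.245, lists from 11 to 15 and interacting lists from 1 to 11. Without C3H CBE array 1 alone the interaction held 25 genes, 18 of them smallest in SV129 and 17 largest in C57, and 152 of 183 genes in the mean were shared with the full set. Of 11 interacting lists 9 were lowest in SV129; the disease-associated microglia, interferon and chemokine lists passed for SV129 against FVB (adjusted p = 0.015, 0.0028 and 6.0e-04) and C57 (2.2e-04, 4.6e-05 and 0.0015) but not C3H (0.62, 0.83 and 0.96).

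With the replicate number as a block there were 164 genes in the mean, 25 in SV129, 35 in FVB, 74 in C57, 7 in C3H, 3 interacting genes, 3035 between PBS strains, 13 lists and 1 interacting list. Calls lost under this block included Isg15 (adjusted p = 0.06) and Atp6ap1l (0.052) in SV129 and Hspa1b (0.055) in the mean. The numbers do not pair the mice: 3 of 12 same-number correlations exceeded 0.1 and 4 of 12 PBS arrays correlated best with their own number. Signal near the lower end of the scale limits the dim genes.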

Other observations

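The test of lysosome members shared with the microglia list was chosen only after the result was seen. A hypothesis was that the rise of the lysosome list comes from the 6 of 32 members it shares with the disease-associated microglia list. Without these members the rise was 0.833 of that with them, 0.17 ± 0.05 (adjusted p = 0.0109), which argues against them as the whole source. The whole list did not pass by camera with an estimated correlation (adjusted p = 0.079). Of the 26 left, 2 passed over all genes and 14 changed by more than 0.1, and the score changed by 0.02 in SV129, 0.15 in FVB, 0.22 in C57 and 0.31 in C3H. The order of the strains leans on C3H CBE array 1. Without it the whole list changed by 0.15 in C3H, against 0.38 with it, 0.18 in FVB and 0.25 in C57.

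SV129 PBS array 1 differed from its replicates in Gfap, at 6.79 against 5.23 and 5.73, and in Cxcl13, at 6.67 against 5.12 and 5.03. The lowest array weights were 0.600 for SV129 PBS array 2 and 0.651 for SV129 PBS array 1.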
